A study of Mus musculus with 46 samples.

How the data were processed

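RNA of RAW264.7 mouse macrophages was measured on 46 Agilent mouse arrays with 60-base oligonucleotide probes. On each array the labelled RNA of the cells was hybridised together with a common reference RNA pool made from several mouse cell lines (Stratagene Universal Mouse Reference), so each spot compares cell RNA with the same reference. Per the labels, the cells were plated overnight in 6-well plates, washed, and then kept in serum-free medium with or without 50 ng/ml lipopolysaccharide (LPS) of E. coli for 6 or 24 h. RNA was extracted with Trizol and labelled through an aminoallyl step. The 46 arrays hold 24 replicate cultures, 22 of them hybridised a second time with the dyes exchanged and 2 of them (media at 6 h, replicates 4 and 6) on 1 array each.

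The arrays were read with the scanner software Agilent Feature Extraction, in version 8.1.1.1 or 9.1.3.1 per the file headers; the name of the tool is taken from the submitters' processing notes. Per the file headers, the mean signal of each spot and its median local background are raw fluorescence intensity in each channel. The deposited processed signals are also intensity, background-subtracted with a spatial detrend and dye-normalised by Feature Extraction through a lowess curve over rank-consistent spots. The deposited log ratio is the log10 of red over green processed signal. Deposited flags of spots (outlier, saturated, well above background) take the value 0 or 1. The values in the series matrix are of mixed kind. For Sigma LPS at both times and for media at 6 h replicates 4 to 6 they are log10 red over green. For the other arrays the authors submitted log2 ratios of cell RNA over reference, already turned for the dye, and how their background was treated is not stated. This was found by comparing each column with the log ratio of its own array.

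The raw mean signals and median backgrounds were used here. Background was removed with the normexp method and an offset of 50, and each array was loess-normalised (limma 3.58.1 in R 4.3.3, data.table in version 1.17.8, statmod 1.5.0, and for figures python 3.11.15 and matplotlib 3.10.9). All ratios were turned to log2 cell RNA over reference. Spots carrying the software's outlier flag, between 0.605% and 60.9% of the spots per array, were left out. The dye effect of each probe, estimated from the complete dye-swap pairs, was subtracted, and the arrays of 1 culture were averaged to 1 value, so that n counts cultures and not arrays. Of the 21318 spots that are not controls, 20868 distinct probes and 19283 genes were formed. Where a gene had several probes (1413 genes, at most 7 probes), the probe with the highest mean log intensity stood for it. A gene was kept when the cell channel was well above background on at least 0.5 of the arrays of 1 group or more, which left 19004 genes. Probes were named by joining the accession in the files to current symbols; 14676 were named by accession, 2721 by a current symbol and 1633 by a synonym, and for 1838 the name in the file was kept. Genes are given by symbol only, and no genome coordinates were assigned.

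All 24 cultures were fitted in 1 linear model with a mean for each of the 6 groups. An additive term was added for the array batch, that is, the software version together with the array design. Batch 2 held media at 6 h replicates 4 to 6 and Sigma LPS at 6 h, and batch 1 held everything else. With this term the effect of LIST LPS at 6 h rests on media replicates 1 to 3 and that of Sigma LPS at 6 h on media replicates 4 to 6. Genes were tested with limma's moderated test (two-sided, prior degrees of freedom 4.9, median residual SD 0.181), with Benjamini-Hochberg adjustment over the genes tested in each comparison. A gene passed at an adjusted p under 0.05. A gene was tested where at least 2 cultures of each group had a value; this minimum was set after the data were seen. Values given as mean ± SD are log2 cell RNA over reference, adjusted for batch, over cultures. The groups follow the sample titles: 1 label field of the Sigma LPS 6 h arrays states 24 h, while their titles and source names state 6 h, and the source name of media 6 h replicate 4 says replicate 3.

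The 26 gene lists were tested with limma's camera with a preset correlation between genes of 0.01. Each list was also tested with an estimated correlation and with fry, and the number of members passing was counted over all genes and adjusted over the list alone. The lists cover inflammatory and interferon signalling, enzymes, metabolism, stress, cell cycle, ribosomes and macrophage functions, and markers of 4 other kinds of cells (fibroblast and matrix, epithelial, lymphocyte, granulocyte and erythroid).

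Of each LPS effect the 10 genes with the largest rise and the 8 with the largest fall were named, among genes past the threshold whose LPS cultures all lay beyond all media cultures. Up to 4 members of each list with the smallest p and 12 fixed genes (Tnf, Il6, Il1b, Il10, Nos2, Ptgs2, Ifnb1, Cxcl10, Ccl5, Tlr2, Tlr4, Cd14) were named as well. Differences between preparations or times named up to 10 genes in each direction. A pair of genes picked by these rules is not reported here. Groups, comparisons, tests, gene lists, this rule and most alternatives were chosen before the data were examined. The alternatives chosen after seeing the data kept the outlier-flagged spots, left out the Cy3 array of Sigma LPS 6 h replicate 1, took the scan period as a fixed or a random block, or set each LPS group against untreated cells of its own scan period. The scan dates in the file headers form 4 periods: media 24 h replicates 1 to 3 with Sigma LPS 24 h; LIST LPS at both times with media 6 h replicates 1 to 3; media 24 h replicates 4 to 6; and media 6 h replicates 4 to 6 with Sigma LPS 6 h.

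Other alternatives changed the background correction, normalisation, filter, probe choice, dye term, batch term, media replicates or weights, used the series matrix, or left out each culture. The fit, not the steps before it, was tested on simulated log ratios. Of 50 genes changed 2-fold in each of the 4 LPS effects, 46, 48, 48 and 43 were recovered. Of 50 changed 1.5-fold, 27, 23, 33 and 29 were. All 50 changed 4-fold were recovered, and 16, 12, 9 and 11 unchanged genes passed. The fit was checked against limma on 6741 complete genes. By the software's criterion, which was 2.6 in batch 1 and the stricter 13 in batch 2, the cell channel was well above background at 84.3% to 98.6% of spots on all arrays but 1 (Cy3, Sigma LPS 6 h replicate 1), where it was so at 61.1%.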

Results

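Gene expression was measured in RAW264.7 cells, a mouse macrophage-like line, with and without LPS, the glycolipid of the outer membrane of Gram-negative bacteria that macrophages sense through Tlr4 and its co-receptor Cd14. A pair of preparations of E. coli LPS were used at 50 ng/ml: an ultrapure one from List Biological Laboratories (LIST LPS) and one from Sigma (Sigma LPS). Each preparation was given for 6 h or 24 h to 3 cultures, and 6 cultures per time were kept in media alone. The design asks which genes each preparation changed at each time, whether the preparations differed, and whether their effects differed between the times. The median cell signal ranged from 203 to 1792 intensity units between arrays. Dye-exchanged arrays of 1 culture correlated at r 0.73 to 0.943 across genes, except for Sigma LPS 6 h replicate 1 (r 0.15), whose Cy3 array had 61.1% of spots well above background. Genes are not independent replicates, so these r describe arrays only.

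LIST LPS at 6 h raised genes of cytokines, chemokines and the interferon response. Csf3, which encodes granulocyte colony-stimulating factor, was 56-fold higher than in media alone (log2 fold change 5.81, SE 0.41; 5.43 ± 0.18, SD, n = 3, against -0.38 ± 0.36, SD, n = 6; adjusted p = 1.18e-09). Cxcl10, an interferon-induced chemokine, was 46.2-fold higher (5.53, SE 0.46), and Cmpk2, a mitochondrial nucleotide kinase induced by interferon, was 31-fold higher (4.95, SE 0.20). The largest fall was that of Kbtbd11 (-3.22, SE 0.21; 0.30 ± 0.03, n = 3, against 3.52 ± 0.47, n = 6). Of 16193 genes tested, 798 rose and 687 fell, and of these 377 and 80 changed at least 2-fold.

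Cytokine genes rose as a group with LIST LPS at 6 h: 12 of 19 tested rose, none fell and 7 did not pass (median log2 fold change 1.04, adjusted p = 1.82e-15, camera), with 15 rising and 1 falling adjusted over the list alone. Il1a, an alarm cytokine, rose by 4.49 (SE 0.28), Il10, an anti-inflammatory cytokine, by 4.12 (SE 0.34), Csf2, a growth factor of myeloid cells, by 2.75 (SE 0.18) and Tnf by 2.69 (SE 0.54, adjusted p = 0.00354). Il6 rose 2.06-fold (1.04, SE 0.14). Of 15 chemokine genes 10 rose and 5 did not pass, with 12 rising over the list alone (median 2.79, adjusted p = 5.33e-16). Ccl3 rose by 4.38, Ccl12 by 4.07, Ccl22, a chemokine for T cells and dendritic cells, by 3.92 and Ccl5 by 2.92. Of 25 interferon response genes 22 rose and 3 did not pass (22 over the list alone, median 2.23, adjusted p = 1.35e-37). Among them were Oasl1, an antiviral protein of the oligoadenylate synthetase family, at 4.03, Gbp4 at 2.70 and Isg20 at 2.23. Ifnb1 itself, the gene of interferon beta, stood at -0.04 (SE 0.11, adjusted p = 0.896).

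Saa3, a serum amyloid of macrophages, rose by 4.69 (SE 0.33) and Acod1, the enzyme that makes itaconate, by 4.57 (SE 0.66). Of 16 genes of nitric oxide, prostaglandin and arginine enzymes 8 rose and 8 did not pass (8 over the list alone, median 0.39, adjusted p = 5.59e-06). They included Odc1, ornithine decarboxylase, at 3.15, Nos2, the inducible nitric oxide synthase, at 2.44 and Gch1 at 1.97. Of 16 NF-kB genes 6 rose, with 9 rising and 1 falling over the list alone (median 0.46, adjusted p = 5.59e-06). Nfkbiz, an atypical nuclear inhibitor of the NF-kB family, was at 3.73 and Traf1 at 1.24. Of 16 signal inhibitors 8 rose and 1 fell, 10 and 1 over the list alone (median 0.72, adjusted p = 1.44e-07), among them Zfp36, which destabilises cytokine mRNA, at 3.07 (saturated on 0.5 of the LIST LPS arrays), Socs3 at 2.95 and Dusp5 at 2.30. Antigen presentation genes rose in 9 of 24, with 11 rising and 2 falling over the list alone (median 0.41, adjusted p = 1.52e-07). The peptide transporter Tap1 was at 3.08 and Cd40 at 2.14. Of 21 matrix protease and coagulation genes 7 rose and 1 fell, 10 and 1 over the list alone (median 0.26, adjusted p = 8.43e-05). Procr, the endothelial protein C receptor, was at 2.20, the protease inhibitor Timp1 at 2.16 and Plau, the urokinase plasminogen activator, at -1.27. Of 25 immediate early factors 7 rose and 1 fell, 9 and 2 over the list alone (median 0.20, adjusted p = 8.39e-05), with Ier3 at 2.52 and Myc at 1.90.

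Macrophage identity genes rose in 6 of 30 and fell in 1, 7 and 2 over the list alone (adjusted p = 0.00411, and 0.394 with an estimated correlation, marked estimated below). The transcription factor Cebpd was at 3.09, the IgG receptor Fcgr1 at 2.15 and the complement gene C1qc at 1.68. Cell cycle genes fell in 5 of 38, also over the list alone (median -0.36, adjusted p = 3.38e-05, and 0.394 estimated), among them Ccna2 at -1.57 and Ccne2 at -1.20, both cyclin genes. Cholesterol synthesis genes fell in 5 of 21, also over the list alone (median -0.17, adjusted p = 0.00481, and 0.138 estimated). Scd2 was at -1.60 and Scd1 at -1.10, both fatty acid desaturases. The other largest falls were Rasa3 at -2.17, N4bp2l1 at -1.90, Lyl1 at -1.78, Slit2 at -1.72, Rbl2 at -1.65 and Chst10 at -1.61. Slit2 and Ccna2 rest on media 6 h replicate 2 alone. Markers of granulocytes and erythroid cells rose in 5 of 13, also over the list alone (median 0.13, adjusted p = 0.00182), among them Lcn2 at 3.24, S100a8 at 1.69, Elane at 0.73 and, named after its values were seen, Mcpt8 at 0.63. Macrophages also express Lcn2 and S100a8. Of the 13 lists that passed, 10 also passed with an estimated correlation, that is, all but macrophage identity, cell cycle and cholesterol synthesis.

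Lists that did not pass with LIST LPS at 6 h were TLR receptors (4 of 20 rose, 4 over the list alone; adjusted p = 0.0861; Tlr3 at 2.45), LXR and lipid efflux (1 rose and 3 fell of 14; adjusted p = 0.288; Abcg1, a cholesterol exporter, at -1.42), glycolysis and hypoxia (3 rose and 1 fell of 21, 3 and 2 over the list alone; adjusted p = 0.833), oxidative stress and NRF2 (2 rose and 1 fell of 24, 4 and 3 over the list alone; adjusted p = 0.81; Gclc at -1.01), unfolded protein and amino acid stress (3 of 19 rose; adjusted p = 0.259; median -0.07 but mean 0.19), lysosome and cathepsins (1 rose and 2 fell of 26; adjusted p = 0.81), osteoclast (1 rose and 1 fell of 13, 3 and 2 over the list alone; adjusted p = 0.645), oxidative phosphorylation (0 of 35; adjusted p = 0.304), ribosomal proteins (2 of 48 fell, 0 over the list alone; adjusted p = 0.388) and ribosome biogenesis (0 of 21; adjusted p = 0.711). Markers of fibroblasts, with 1 of 16 lower, of epithelial cells, with 0 of 12 passing, and of lymphocytes, with 1 of 15 higher and 1 lower, each had an adjusted p of 0.645. Tlr4 stood at -0.02 (adjusted p = 0.962) and Cd14 at 0.87 (SE 0.40, adjusted p = 0.224). Il1b, Ptgs2 and Tlr2 had fewer than 2 cultures with usable spots in a group and were not tested. Without a batch term 2388 genes passed in place of 1485, and with the outlier-flagged spots kept 2412.

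**Figure D1:**
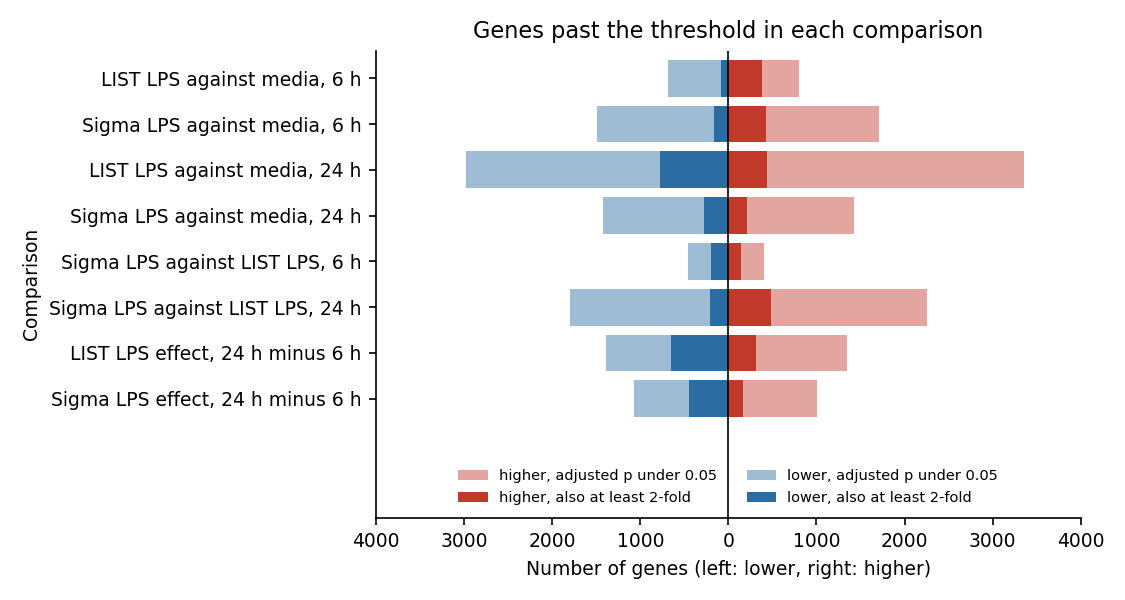
Number of genes past an adjusted p of 0.05 in each comparison, higher to the right and lower to the left of 0, with those also changed at least 2-fold in the darker shade. LIST LPS at 24 h had the highest count, 3356 higher and 2981 lower.

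Sigma LPS at 6 h raised inflammatory cytokines, chemokines and interferon response genes as well. Csf3 was 50.1-fold higher than in media (5.65, SE 0.41; 5.27 ± 1.41, SD, n = 3, against -0.38 ± 0.36, SD, n = 6; adjusted p = 3.78e-09). Il1b, the gene of interleukin 1 beta, was 43.7-fold higher (5.45, SE 0.55), Saa3 32.6-fold (5.03, SE 0.33) and Ptgs2, the inducible cyclooxygenase, 21.3-fold (4.41, SE 0.44). Plau had the largest fall (-2.6, SE 0.14; 0.08 ± 0.05, n = 3, against 2.68 ± 0.24, n = 6). Of 18752 genes tested, 1707 rose and 1491 fell, of which 422 and 168 changed at least 2-fold.

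Of 20 cytokine genes 11 rose with Sigma LPS at 6 h and none fell, 12 over the list alone (median 0.74, adjusted p = 1.71e-09). Il10 was at 4.23 (SE 0.34), Osm at 1.5, Il27 at 1.47 and Tnf at 1.40 (SE 0.44, adjusted p = 0.0403). Il6 stood at 0.40 (SE 0.14, adjusted p = 0.0628). Of 18 chemokine genes 10 rose, also over the list alone (median 1.19, adjusted p = 5.86e-10). Among these were the monocyte chemokines Ccl7 at 4.74 and Ccl2 at 4.24, the neutrophil chemokine Cxcl2 at 4.71, Ccl3 at 4.35, Cxcl10 at 3.56 and Ccl5 at 1.64. Of 39 interferon response genes 34 rose and 5 did not pass, with 36 rising and 1 falling over the list alone (median 1.38, adjusted p = 1.75e-29). Oasl1 was at 4.37, Cmpk2 at 4.13, the antiviral Rsad2 at 4.03 and the GTPase Gbp2 at 2.83. Ifnb1 stood at 0.18 (adjusted p = 0.328). Immediate early factors rose in 17 of 30 and fell in 3, 18 and 3 over the list alone (median 0.73, adjusted p = 3e-07), with Ier3 at 2.27, Myc at 2.21 and Fosl1 at 1.78. Matrix protease and coagulation genes rose in 13 of 29 and fell in 1, 15 and 1 over the list alone (median 0.37, adjusted p = 4.51e-06), with Serpinb2, a plasminogen activator inhibitor, at 4.65 and Procr at 2.29. These 5 lists also passed with an estimated correlation.

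Other lists passed with the preset correlation alone. NF-kB genes rose in 12 of 22, 13 over the list alone (median 0.53, adjusted p = 4.65e-09, and 0.0501 estimated), with Nfkbiz at 2.98 and Tnfaip3, a deubiquitinase that restrains NF-kB, at 2.17. Signal inhibitors rose in 7 of 19, 8 over the list alone (median 0.39, adjusted p = 1.42e-06, and 0.0603 estimated), with Socs3 at 4.37 and Zfp36 at 3.24. Genes of nitric oxide, prostaglandin and arginine enzymes rose in 8 of 16, with 1 falling over the list alone (median 0.38, adjusted p = 5.82e-05, and 0.0689 estimated), with Acod1 at 3.96 and Nos2 at 1.91. Antigen presentation genes rose in 12 of 26 and fell in 1, 13 and 1 over the list alone (adjusted p = 1.86e-05, and 0.0603 estimated). Cd274, the ligand of an inhibitory T-cell receptor, was at 1.93. Ribosomal protein genes rose in 21 of 52 and fell in 3, 24 and 4 over the list alone (median 0.33, adjusted p = 7.42e-05, and 0.531 estimated), with Rpl19 at 1.72. Unfolded protein genes rose in 6 of 26 (median 0.12, adjusted p = 0.0318, and 0.531 estimated), with Gadd45b at 2.23 and Chac1 at 1.43. Macrophage identity genes rose in 12 of 36 and fell in 7, 15 and 8 over the list alone (median 0.36, adjusted p = 0.0394, and 0.633 estimated). Fcgr1 was at 2.81 and Csf1r, the receptor of the macrophage growth factor, at -2.08. Granulocyte and erythroid markers rose in 2 of 15 (median 0.17, adjusted p = 0.0192, and 0.0941 estimated), namely S100a8 at 2.74 and Lcn2 at 2.43.

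Other falls with Sigma LPS at 6 h were those of Abcg1 at -2.36, N4bp2l1 at -2.12, Gpr183, an oxysterol receptor, at -2.06, Cd72 at -1.93, Chst10 at -1.89 and Ifi30, a lysosomal thiol reductase, at -1.85. Lists that did not pass were TLR receptors (7 rose and 3 fell of 25; adjusted p = 0.497; Cd14 at 2.12), cell cycle (1 rose and 8 fell of 51, 2 and 10 over the list alone; adjusted p = 0.0988), cholesterol synthesis (3 rose and 3 fell of 27; adjusted p = 0.609), LXR and lipid efflux (4 rose and 5 fell of 20; adjusted p = 0.416), glycolysis and hypoxia (6 rose and 2 fell of 26; adjusted p = 0.416; the glucose transporter Slc2a1 at 2.34), oxidative stress and NRF2 (7 rose and 7 fell of 29, 8 and 8 over the list alone; adjusted p = 0.81; median -0.01 but mean 0.18; the metallothionein Mt2 at 3.58), lysosome and cathepsins (5 rose and 5 fell of 32; adjusted p = 0.903), osteoclast (6 rose and 3 fell of 17; adjusted p = 0.242), oxidative phosphorylation (9 rose and 8 fell of 38, 12 and 9 over the list alone; adjusted p = 0.309), ribosome biogenesis (5 rose and 4 fell of 27; adjusted p = 0.906), fibroblast (0 of 16; adjusted p = 0.609), epithelial (1 of 13 rose; adjusted p = 0.416) and lymphocyte markers (1 of 18 fell, 0 over the list alone; adjusted p = 0.576). Tlr2 stood at 0.06 (adjusted p = 0.845) and Tlr4 at -0.18 (adjusted p = 0.376). For Csf3 the spread between Sigma LPS 6 h cultures was wide (an SD of 1.41 against 0.18 with LIST LPS). Without the Cy3 array of replicate 1, 3535 genes passed in place of 3198. With media replicates 4 and 6, measured on 1 array each, left out 890 genes passed, and within batch 2 alone 1542.

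**Figure D2:**
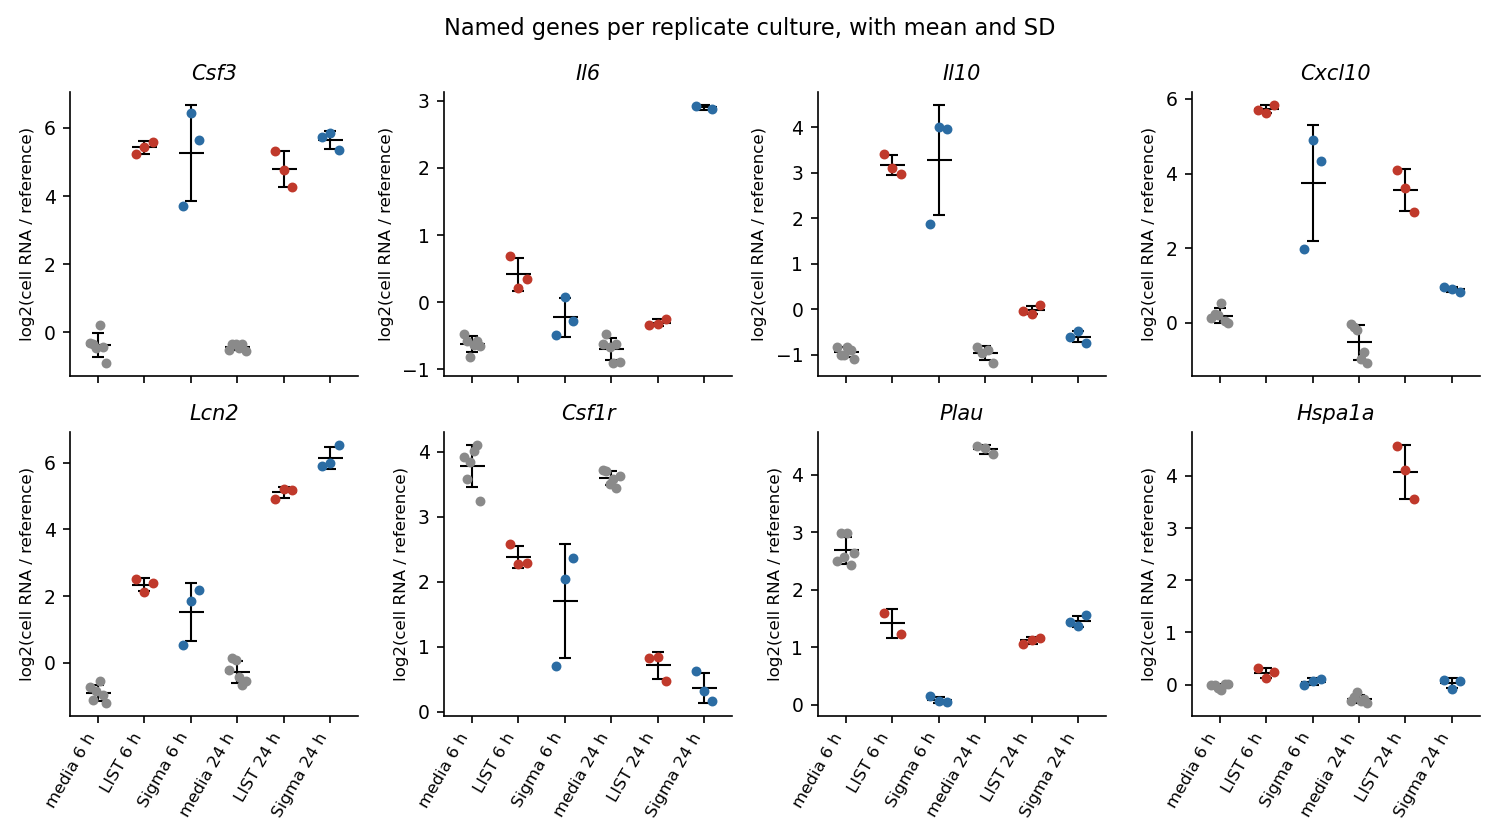
Log2 cell RNA over reference of 8 genes in each culture (dots), adjusted for batch, with the group mean and SD (bars), over media, LIST LPS and Sigma LPS at 6 h and 24 h. Il6 averaged 2.90 with Sigma LPS and -0.30 with LIST LPS at 24 h, and Hspa1a 0.02 and 4.08.

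With LIST LPS at 24 h Saa3 was 52.2-fold higher than in media (5.71, SE 0.29; 5.90 ± 0.14, SD, n = 3, against 0.19 ± 0.12, SD, n = 6; adjusted p = 4.44e-12), Lcn2, the iron-sequestering lipocalin 2, 41.7-fold (5.38, SE 0.26) and Csf3 37.3-fold (5.22, SE 0.36). Hspa1a, an inducible heat shock protein, was 20.5-fold higher (4.36, SE 0.13). Csf1r was 7.36-fold lower (-2.88, SE 0.24). Of 16939 genes tested, 3356 rose and 2981 fell, of which 442 and 780 changed at least 2-fold.

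The LIST LPS 24 h arrays share no scan period with media at 24 h, so the effect was also computed against each set of 3 media cultures. In total 1929 of 11885 genes tested in all 3 settings (media 24 h replicates 1 to 3, media 24 h replicates 4 to 6, and media 6 h of the same scan period) changed in the same direction in each, 1101 higher and 828 lower, and 49 passed in opposite directions. Genes with like values in all 3 were Saa3 (5.61, 5.80 and 5.64), Lcn2 (5.10, 5.66 and 6.01), Csf3 (5.19, 5.25 and 5.17), Hspa1a (4.32, 4.39 and 4.10), Cxcl10 (3.65, 4.49 and 3.36), Cxcl2 (4.37, 3.70 and 3.63), Ifit2 (3.18, 3.61 and 3.70) and Csf1r (-2.93, -2.83 and -3.07). Genes among the largest changes that did not pass against the media of the same scan period were Slc26a11 (3.67 against all media, 0.45 there), Npr3 (3.48 and 0.72, a second probe 0.41 against all media), the intermediate filament gene Vim (-3.79 and -0.62) and Rps27a (-3.15 and 0.04). Txnip, a regulator of thioredoxin, lay at -3.07 against all media and -1.99 there. Measured at 24 h in media replicates 1 to 3 only, COX2, the mitochondrially encoded cytochrome oxidase subunit, lay at -5.12 against these and -1.80 there, Plau at -3.33 and -1.57, Scd2 at -3.16 and -1.37, the leukotriene receptor gene Cysltr1 at -3.09 and -2.10, and Saa1 at 3.67 and 2.01.

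Of 34 interferon response genes 20 rose with LIST LPS at 24 h and none fell, 23 over the list alone (median 0.68, adjusted p = 1.97e-08, and 0.158 estimated), and 13 of 25 rose in all 3 settings. Oasl1 was at 2.85, Cmpk2 at 2.43, Isg20 at 2.17 and Gbp4 at 1.35. Ifnb1 stood at 0.02 (adjusted p = 0.91). Of 16 chemokine genes 8 rose, 9 over the list alone (median 0.50, adjusted p = 0.000603, and 0.147 estimated), and 6 of 12 in all 3 settings. Ccl12 was at 3.17 and Ccl5 at 3.00. Of 18 cytokine genes 10 rose and 1 fell, 10 and 2 over the list alone (median 0.43, adjusted p = 0.0054, and 0.158 estimated), and 2 of 12 rose in all 3 settings. Il1a was at 2.66, Tnf at 1.47 (SE 0.49), Il10 at 0.95 (SE 0.31) and Il6 at 0.39 (SE 0.12, adjusted p = 0.0173). Against media of the same scan period Tnf stood at 0.10 (adjusted p = 0.892) and Il6 at 0.32 (adjusted p = 0.0679), and against media replicates 1 to 3 Il6 stood at 0.28 (adjusted p = 0.11). Genes of nitric oxide, prostaglandin and arginine enzymes rose in 10 of 15 and fell in 2, 10 and 3 over the list alone (median 0.39, adjusted p = 0.0144, and 0.212 estimated), with Nos2 at 2.17 and the prostaglandin E synthase Ptges at 1.15.

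Oxidative phosphorylation genes fell in 25 of 36 and none rose, 27 over the list alone (median -0.69, adjusted p = 1.37e-10, and 0.147 estimated), and 9 of 21 fell in all 3 settings. Cox7a2 was at -2.54 (-1.30 against media of the same scan period, as in the brackets below) and Cox6c at -1.70 (-1.01). Ribosomal protein genes fell in 33 of 47, with 34 falling and 1 rising over the list alone (median -0.61, adjusted p = 1.37e-10, and 0.158 estimated), and 13 of 44 fell in all 3 settings. Rpl12 was at -1.81 (-0.69) and Rpl3 at -1.21 (-0.91). Glycolysis and hypoxia genes fell in 13 of 23 and rose in 2, the same over the list alone (median -0.67, adjusted p = 5.57e-05, and 0.0291 estimated), and 7 of 13 fell in all 3 settings. Pdk1, a kinase that restrains pyruvate dehydrogenase, was at -1.86 (-0.87), the pyruvate kinase Pkm at -1.43 (-1.0) and lactate dehydrogenase Ldha at -1.34 (-0.59). Oxidative stress genes fell in 12 of 26 and rose in 3 (median -0.45, adjusted p = 0.00201, and 0.194 estimated), with Txn1, thioredoxin, at -2.75 (-1.24). Lysosomal genes fell in 14 of 27 and rose in 2, 16 and 2 over the list alone (median -0.51, adjusted p = 0.000674, and 0.158 estimated). Lamp1 was at -1.80 (-1.15) and Psap at -1.06, and against untreated cells of the same scan period the direction of this list turned (adjusted p = 0.414; Psap at 0.07).

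Cholesterol synthesis genes fell in 9 of 23 and rose in 1, 10 and 1 over the list alone (median -0.41, adjusted p = 0.000603, and 0.158 estimated), with Hmgcs1 at -1.31 (-2.37 against media of the same scan period) and Srebf1 at -1.22 (-0.72). LXR and lipid efflux genes fell in 8 of 15 and rose in 1 (median -0.44, adjusted p = 0.0155, and 0.158 estimated). The scavenger receptor Cd36 was at -2.23 (not tested there) and Abcg1 at -1.58 (-0.84). Cell cycle genes fell in 19 of 45 and rose in 3 (median -0.44, adjusted p = 0.000603, and 0.405 estimated), with Top2a, the topoisomerase of dividing cells, at -2.44 (-2.76 in the same period) and Bub1 at -2.18 (-0.51, not passing). Against media replicates 4 to 6 alone the direction of the list turned (adjusted p = 0.659). Macrophage identity genes fell in 12 of 32 and rose in 2, 12 and 4 over the list alone (median -0.18, adjusted p = 0.014, and 0.401 estimated), with Adgre1, the macrophage marker F4/80, at -2.11 (-0.60, not passing) and Fcgr1 at 2.76 (2.52). Against untreated cells of the same scan period its direction turned (adjusted p = 0.999). Lymphocyte markers rose in 8 of 17 and fell in 1 (median 0.30, adjusted p = 0.00757, and 0.147 estimated), with Ncr1 at 0.93 (0.52) and Lck at 0.63 (0.24, not passing). Granulocyte and erythroid markers rose in 5 of 13, with 1 falling over the list alone (median 0.22, adjusted p = 0.0492, and 0.194 estimated), with S100a8 at 2.95, and turned with signal on every array (adjusted p = 0.821). In all 3 settings 0 of 12 lysosomal, 3 of 26 cell cycle, 4 of 23 macrophage identity, 3 of 15 oxidative stress, 3 of 9 cholesterol synthesis and 2 of 7 LXR genes fell, and 1 of 14 lymphocyte, 3 of 9 granulocyte and erythroid and 4 of 9 nitric oxide, prostaglandin and arginine genes rose.

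Lists that did not pass with LIST LPS at 24 h were NF-kB (5 rose and 1 fell of 19; adjusted p = 0.13; Tnfaip3 at 2.37), signal inhibitors (6 rose and 3 fell of 18, 7 and 3 over the list alone; adjusted p = 0.0786; Dusp5 at 2.51), TLR receptors (3 rose and 8 fell of 24, 4 and 8 over the list alone; adjusted p = 0.0959; Tlr7 at -2.20, Tlr4 at -0.62), antigen presentation (7 rose and 4 fell of 25; adjusted p = 0.223; Tap1 at 1.38), unfolded protein (7 rose and 3 fell of 20; adjusted p = 0.0702; Ddit3 at 2.13 and Xbp1 at -2.74), matrix proteases (7 rose and 2 fell of 24; adjusted p = 0.327; Timp1 at 3.05), osteoclast (3 rose and 4 fell of 14; adjusted p = 0.578; median 0.09 but mean -0.12), immediate early factors (10 rose and 2 fell of 28, 11 and 2 over the list alone; adjusted p = 0.0959), ribosome biogenesis (2 rose and 8 fell of 23; adjusted p = 0.0707), fibroblast (0 of 15; adjusted p = 0.914) and epithelial markers (1 of 12 rose; adjusted p = 0.381). Cd14 stood at -1.54 (SE 0.36, adjusted p = 0.00206) against all media and at -0.74 (adjusted p = 0.053) against media of the same scan period. Il1b and Ptgs2 were not tested, and Tlr2 stood at -0.33 (adjusted p = 0.2). With scan period as a random block 2563 genes passed in place of 6337, and against media replicates 4 to 6 alone 4219.

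**Figure D3:**
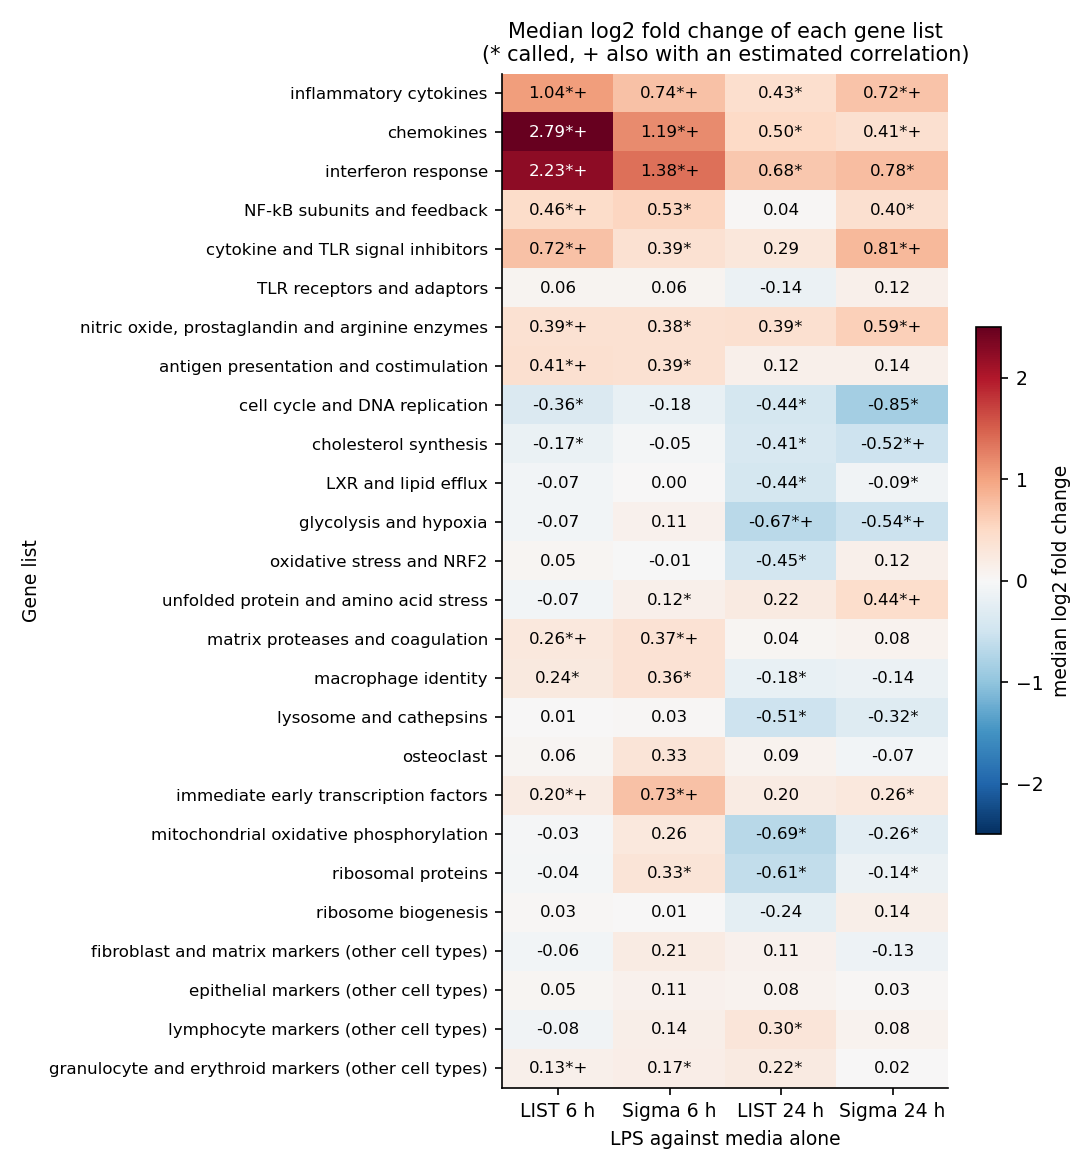
Median log2 fold change of the 26 gene lists in the 4 effects of LPS against media. A star marks a camera adjusted p under 0.05 and a plus sign one that also passed with an estimated correlation. Oxidative phosphorylation lay at -0.69 with LIST LPS and -0.26 with Sigma LPS at 24 h, and at -0.03 and 0.26 at 6 h.

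Sigma LPS at 24 h raised genes of cytokines and of nitric oxide, prostaglandin and arginine enzymes and lowered genes of glycolysis and cholesterol synthesis. Ptgs2 was 140-fold higher than in media (7.13, SE 0.47; 5.28 ± 0.24, SD, n = 2, against -1.85 ± 0.19, SD, n = 4; adjusted p = 5.1e-08). Lcn2 was 85.7-fold higher (6.42, SE 0.26), Csf3 67-fold (6.07, SE 0.36) and Il1b 58.7-fold (5.88, SE 0.49). With Sigma LPS at 24 h the spots of Lcn2 and Casp9 were saturated on 0.83 and those of Cxcl2 on 0.67 of the arrays, which holds their values down. Csf1r was 9.34-fold lower (-3.22, SE 0.24) and Mycn, a growth-promoting transcription factor, fell by 3.41 on the log2 scale (SE 0.39). Of 16031 genes tested, 1426 rose and 1425 fell, of which 212 and 276 changed at least 2-fold.

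Of 20 cytokine genes 10 rose with Sigma LPS at 24 h and 1 fell, 11 and 1 over the list alone (median 0.72, adjusted p = 3.42e-09), with Il1a at 5.12, Tnf at 3.67, Il6 at 3.60 (SE 0.14) and Il23a at 1.55. Il10 stood at 0.36 (SE 0.31, adjusted p = 0.471). Of 15 chemokine genes 6 rose, with 7 rising and 1 falling over the list alone (median 0.41, adjusted p = 1.93e-05), with Ccl7 at 4.21, Cxcl2 at 3.91, Ccl5 at 3.64, Ccl2 at 2.87 and Cxcl10 at 1.42. Signal inhibitors rose in 10 of 15 and fell in 1 (median 0.81, adjusted p = 6.28e-08), with Socs3 at 3.74 and Zfp36 at 2.93. Genes of nitric oxide, prostaglandin and arginine enzymes rose in 8 of 14 and fell in 1, 10 and 1 over the list alone (median 0.59, adjusted p = 1.84e-06). The arginine transporter Slc7a2 was at 1.93 and Nos2 at 1.33. Unfolded protein and amino acid stress genes rose in 13 of 25, 14 over the list alone (median 0.44, adjusted p = 1.91e-08), with Gadd45b at 2.48, the chaperone Hspa5 at 2.40 and Ddit3 at 2.28. Glycolysis and hypoxia genes fell in 14 of 25, with 16 falling and 1 rising over the list alone (median -0.54, adjusted p = 2.47e-11), with Pdk1 at -1.98, the phosphofructokinase Pfkl at -1.31 and Gpi1 at -1.28. Cholesterol synthesis genes fell in 11 of 21, 12 over the list alone (median -0.52, adjusted p = 1.08e-06), with Scd2 at -2.55 and Scd1 at -1.78. These 7 lists also passed with an estimated correlation.

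Of 35 interferon response genes 25 rose, 29 over the list alone (median 0.78, adjusted p = 5.62e-16, and 0.0762 estimated), with Oasl1 at 4.36, Rsad2 at 3.93 and Irf7, the master regulator of interferon genes, at 2.63. Ifnb1 stood at 0.13 (adjusted p = 0.392). Cell cycle genes fell in 25 of 43, 29 over the list alone (median -0.85, adjusted p = 8.76e-14, and 0.0948 estimated), with Kif23 at -2.84, Top2a at -2.70 and Ccnb1, cyclin B1, at -2.24. A second probe of Kif23 gave -0.04. NF-kB genes rose in 8 of 19, with 9 rising and 1 falling over the list alone (median 0.40, adjusted p = 7.98e-05, and 0.144 estimated), with Nfkbiz at 2.85. Immediate early factors rose in 7 of 29 and fell in 1, 8 and 1 over the list alone (adjusted p = 0.0176, and 0.0948 estimated), with Myc at 1.87 and Klf2 at -1.32. Lysosomal genes fell in 12 of 31, with 1 rising over the list alone (median -0.32, adjusted p = 0.000242, and 0.126 estimated), with Lamp1 at -1.78 and the cathepsin Ctss at -1.43. Oxidative phosphorylation genes fell in 9 of 36, 13 over the list alone (median -0.26, adjusted p = 0.000267, and 0.284 estimated), with Fh1 at -0.94. LXR and lipid efflux genes fell in 5 of 16 and rose in 2 (median -0.09, adjusted p = 0.0211, and 0.227 estimated), with Abcg1 at -2.11. Ribosomal protein genes fell in 5 of 51, 3 over the list alone (median -0.14, adjusted p = 0.048, and 0.676 estimated).

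Other falls with Sigma LPS at 24 h were those of Plau at -2.99, D17H6S56E-5 at -2.97, Anln at -2.74, where a second probe gave -0.06, and Cysltr1 at -2.58. Lists that did not pass were TLR receptors (2 rose and 3 fell of 21; adjusted p = 0.738; median 0.12 but mean -0.04), antigen presentation (5 rose and 2 fell of 24, 7 and 3 over the list alone; adjusted p = 0.0946), oxidative stress and NRF2 (5 rose and 5 fell of 28; adjusted p = 0.829; the autophagy receptor Sqstm1 at 3.12 and the peroxiredoxin Prdx1 at least 1.96-fold higher, its spots being saturated), matrix proteases (6 rose and 4 fell of 26, 8 and 4 over the list alone; adjusted p = 0.711; Procr at 3.28 and Serpinb2 at 3.25), macrophage identity (3 rose and 6 fell of 31, 4 and 6 over the list alone; adjusted p = 0.0946; the integrin Itgb2 at -2.44), osteoclast (3 rose and 5 fell of 13, 3 and 6 over the list alone; adjusted p = 0.23; Dcstamp at -1.55), ribosome biogenesis (1 rose and 4 fell of 21, 2 and 5 over the list alone; adjusted p = 0.732; median 0.14 but mean -0.04), fibroblast (0 of 16; adjusted p = 0.404), epithelial (1 of 13 fell; adjusted p = 0.984), lymphocyte (2 of 16 rose; adjusted p = 0.375) and granulocyte and erythroid markers (2 of 11 rose; adjusted p = 0.0551). Tlr4 stood at -0.25 (adjusted p = 0.191) and Cd14 at 0.47 (adjusted p = 0.403). Tlr2 was not tested. Without Sigma LPS 24 h replicate 1, 1716 genes passed in place of 2851.

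Batch and preparation, which coincide at 6 h, cannot be told apart. Ccl22 was 9.06-fold lower with Sigma LPS than LIST LPS (-3.18, SE 0.22, adjusted p = 3.27e-09), at 1.0 ± 0.42 against 4.18 ± 0.29 (SD, n = 3 each). Csf2 (-2.49, SE 0.25) and Ccl5 (-1.29, SE 0.35, adjusted p = 0.0316) were lower too. Of 16015 genes tested 409 were higher and 458 lower with Sigma LPS, of which 149 and 201 differed at least 2-fold. For the central cytokines the difference did not pass: Tnf -1.29 (SE 0.69, adjusted p = 0.319), Il6 -0.64 (SE 0.20, adjusted p = 0.068), Il10 0.11 (SE 0.48, adjusted p = 0.93), Nos2 -0.53 (SE 0.45, adjusted p = 0.55) and Cxcl10 -1.98 (SE 0.65, adjusted p = 0.0789). Ifnb1 stood at 0.22 (adjusted p = 0.485), Tlr4 at -0.16 (adjusted p = 0.672) and Cd14 at 1.25 (adjusted p = 0.222).

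Further genes lower with Sigma LPS at 6 h were Clvs1 (size unknown, its Sigma spots at background), Eny2 (-3.58) and the desmosomal cadherin Dsg3 (-3.54). Others were Ift52 (-2.81), the homeobox genes Alx1 (-2.66) and Shox2 (-2.6), Pcif1 (-2.55) and Paip1 (-2.5). Higher with Sigma LPS were COX2 (2.90), Ahsa1 (2.88) and Klhl3 (2.30), though a second probe of Klhl3 stood at 0.15 with LIST LPS and -0.20 with Sigma LPS against media. Plpbp, H1f8, Slc39a11, Fmc1, Gp1bb and Akt1s1 also passed as higher. Their cell signal was saturated on every array of LIST LPS and of media replicates 1 to 3 at 6 h, so the LIST LPS effect on them was not measurable and the size of the difference is not known. A second probe of Plpbp stood at 0.36 with LIST LPS and -0.34 with Sigma LPS. Without a batch term the direction of all of these named genes but H1f8 turned, as did that of the ribosomal list below (adjusted p = 0.379). Of the 26 lists 2 passed: interferon response genes were lower with Sigma LPS in 4 of 25 and higher in 1, 9 and 1 over the list alone (median -0.50, adjusted p = 0.000211, and 0.893 estimated), and ribosomal protein genes higher in 5 of 48 and lower in 1, 12 and 1 over the list alone (median 0.44, adjusted p = 0.000211, and 0.893 estimated). The count depends on the batch term, with 4526 genes without it, and on the media replicates of 1 array each, with 246 genes without them. Leaving out LIST LPS 6 h replicate 2 gave 459, media replicate 1 549 and media replicate 4 569, in place of 867.

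The effects of the preparations at 6 h correlated at r 0.47 across 16015 genes, which are not independent replicates. With the batch term each effect rests on its own media cultures, and simulated data with no shared effect gave r 0 (r 0.472 with the media split by hand over 15732 genes). Without a batch term r was 0.239. Of 681 genes passing with both preparations 655 (96.2%) changed in the same direction. Of the genes that rose, 791 with LIST LPS and 1395 with Sigma LPS, 308 were shared where 68.9 would be shared by chance. Of those that fell, 681 and 1226, 347 were shared where 52.1 would be.

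**Figure D4:**
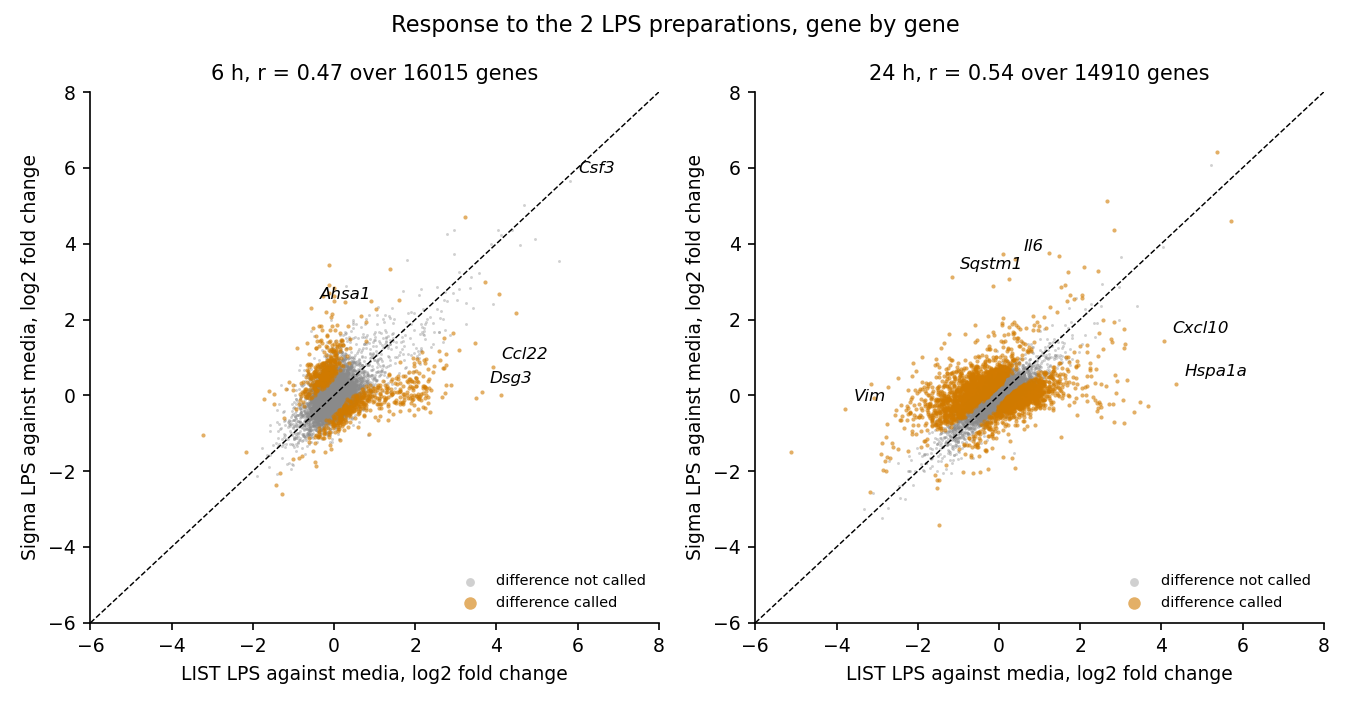
Log2 fold change with LIST LPS (horizontal) and Sigma LPS (vertical) against media at 6 h (left) and 24 h (right), 1 dot per gene, with genes that differ between the preparations in orange and the line of equal effects dashed. The correlation across genes was 0.47 at 6 h and 0.54 at 24 h.

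At 24 h, Sigma LPS gave 9.22-fold more Il6 RNA than LIST LPS (3.21, SE 0.16; 2.90 ± 0.04, n = 2, against -0.30 ± 0.05, n = 3; adjusted p = 3.26e-11), and 4.58-fold more Tnf (2.20, SE 0.49, adjusted p = 0.00429). Tnf could not be tested against its own scan period, and untreated cells of these periods differed by -1.48. LIST LPS gave 16.6-fold more Hspa1a (-4.06, SE 0.15; 0.02 ± 0.10 against 4.08 ± 0.51, n = 3 each; adjusted p = 4.9e-14), more Timp1 (-3.18, SE 0.20) and more Cxcl10 (-2.65, SE 0.46). Of 14941 genes tested 2252 were higher and 1796 lower with Sigma LPS, of which 486 and 209 differed at least 2-fold. Since the arrays of the preparations were scanned in separate periods, each group was also set against untreated cells of its own period, media 24 h replicates 1 to 3 for Sigma LPS and media 6 h replicates 1 to 3 for LIST LPS. With these, 1862 genes passed, and 935 (23.6%) of 3959 genes tested in both settings passed in the same direction in both.

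The genes that passed in both settings included Il6 (3.17 against its own period), Hspa1a (-3.84), Timp1 (-3.44), Cxcl10 (-2.36), the selective autophagy receptor Sqstm1 (4.28 directly and 2.51), the secreted protein gene Wfdc18 (3.62 and 1.64), Txnip (3.00 and 1.31), Adgre1 (2.98 and 1.27) and the homeobox gene Otx1 (-2.95 and -1.04). Ccl5 stood at 0.64 directly (adjusted p = 0.0568) and was higher with Sigma LPS by 1.1 against its own period. Those that passed directly but not against their own period were COX2 (3.61 and 0.30), Rps27a (3.46 and -0.26), Vim (3.43 and -0.61), Ccl2 (3.02 and 1.37), Rps27 (2.97 and -0.03), Cd14 (2.01 and 0.64), Tlr4 (0.38 and 0.36), Nos2 (-0.84 and -1.07), Slc26a11 (-3.95 and -0.03), Serpinb9c (-3.75 and -1.02), Npr3 (-3.66 and -0.23), Dzip1 (-3.54 and -0.66, its LIST LPS effect being 2.83 with this probe and 0.76 with a second), Hes5 (-3.09 and -0.30) and Nppb (-3.03 and -0.83). Cenpm stood lower with Sigma LPS at -3.80 but could not be tested against its own period, and untreated cells of these periods differed by -2.96. Il10 stood at -0.59 (adjusted p = 0.206) and Ifnb1 at 0.11 (adjusted p = 0.493).

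Of the 26 lists 6 passed at 24 h, none with an estimated correlation. Ribosomal protein genes were higher with Sigma LPS in 23 of 46 and lower in 1, 26 and 1 over the list alone (median 0.49, adjusted p = 1.7e-06, and 0.614 estimated). Oxidative phosphorylation genes were higher in 16 of 33 (median 0.38, adjusted p = 0.000204, and 0.614 estimated). Signal inhibitors were higher in 7 of 15 (median 0.48, adjusted p = 0.00206), oxidative stress and NRF2 genes in 9 of 25 and lower in 1, 11 and 1 over the list alone (adjusted p = 0.00162), each with an adjusted p = 0.614 with an estimated correlation. Unfolded protein genes were higher in 7 of 19, 8 over the list alone (median 0.35, adjusted p = 0.033, and 0.647 estimated), and lymphocyte markers were lower in 6 of 16, 7 over the list alone (median -0.19, adjusted p = 0.0405, and 0.614 estimated). The cytokine list, with 7 of 18 higher and 2 lower, had an adjusted p of 0.11. Against untreated cells of the own scan period signal inhibitors (adjusted p = 0.0217), oxidative stress (adjusted p = 0.0464) and unfolded protein genes (adjusted p = 0.0146) still passed, and ribosomal proteins (adjusted p = 0.219), oxidative phosphorylation (adjusted p = 0.102) and lymphocyte markers (adjusted p = 0.396) did not. NF-kB (adjusted p = 0.0156) and ribosome biogenesis (adjusted p = 1.5e-08) newly passed as higher, and cell cycle (adjusted p = 7.99e-05), glycolysis (adjusted p = 0.000167) and matrix proteases (adjusted p = 0.000663) as lower. Lysosome (adjusted p = 0.000167) and LXR (adjusted p = 0.0156) turned to lower. With media 1 to 3 for LIST LPS and 4 to 6 for Sigma LPS cell cycle turned to higher (adjusted p = 0.00234). Without LIST LPS 24 h replicate 3, 2582 genes passed in place of 4048, and with scan period as a random block 750.

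The effects of the preparations at 24 h correlated at r 0.54 across 14910 genes. Both effects use the same media cultures, which alone gives r 0.369 in simulated data (covariance 0.0095, against 0.1238 observed). With media replicates 1 to 3 for LIST LPS and 4 to 6 for Sigma LPS, r was 0.125 (covariance 0.0339) across 11170 genes, and with untreated cells of the own scan period 0.625.

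**Figure D5:**
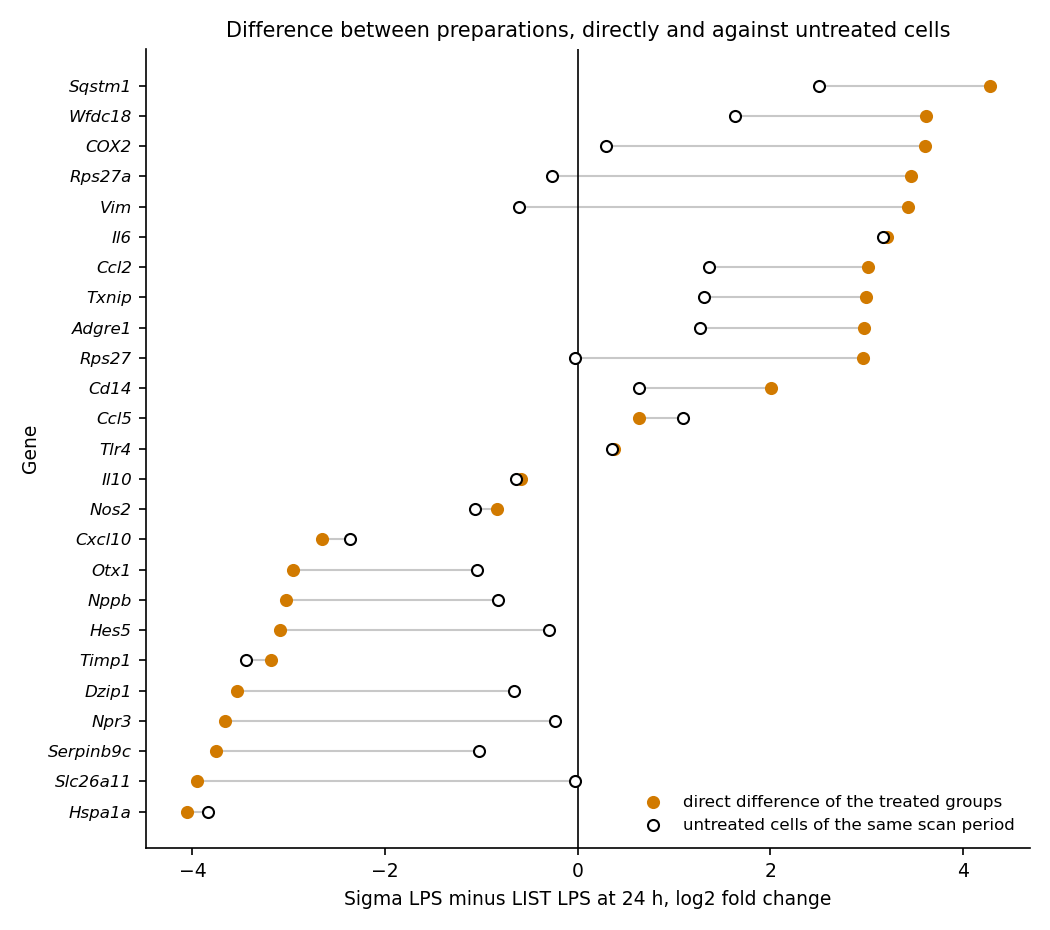
Log2 difference between Sigma LPS and LIST LPS at 24 h for the named genes, as the direct difference of the treated groups (orange) and with each group set against untreated cells of its own scan period (open circles). Il6 lay at 3.21 and 3.17, Hspa1a at -4.06 and -3.84, and Vim at 3.43 and -0.61.

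The effect of LIST LPS differed between the times for 2735 of 15526 genes, 1347 with a higher and 1388 with a lower value at 24 h, of which 316 and 647 differed at least 2-fold. The LIST LPS cultures of both times share a scan period, which the media at 24 h do not, so the direct difference between these cultures is given as the second value for each gene. Among the genes lower at 24 h in both were Ccl22 (-3.59, SE 0.20, and -3.45), the RNA sensor Ifih1 (-3.52 and -3.16), Cebpd (-3.36 and -3.04), Il10 (-3.17 and -3.19), Cd14 (-2.41 and -1.61) and Il6 (-0.65 and -0.72, but 0.01 in the series matrix). The direct difference was smaller for Ccl3 (-4.43 and -1.34), Ccl4 (-3.47 and -1.52) and Litaf (-3.44 and -1.61). With LIST LPS at 24 h Ccl3 stood at -0.74, 0.66 and 3.04 and Ccl4 at -0.41, 1.18 and 2.34 against media 24 h replicates 1 to 3, media 24 h replicates 4 to 6 and media of the same scan period, cultured for 6 h. Litaf stood at -0.73 (adjusted p = 0.0813) against the last. Higher at 24 h in both were Hspa1a (4.11 and 3.85), Kbtbd11 (3.51 and 0.93), Agbl1 (3.13 and 1.39) and Olfr50 (2.87 and 1.17). Npr3 (3.42 and 0.66), Capn5 (3.41 and 0.48), Cenpm (3.36 and 0.78), Pou1f1 (3.36 and 0.37), the immunoglobulin transporter Pigr (3.21 and 0.86) and Serpinb9c (3.04 and 0.86) did not pass in the direct difference. COX2 (-4.83 and -1.51) and Vim (-4.26 and -1.09) were lower in both. Rps27a (-3.70 and -0.51) did not pass in the direct difference. Tlr4 was lower at -0.60 (-0.59 directly). Tnf (-1.22, adjusted p = 0.277) and Cxcl10 (-1.46, adjusted p = 0.102) did not pass, but did in the direct difference (-2.59 and -2.17). Nos2 (-0.27, adjusted p = 0.715), Ccl5 (0.08, adjusted p = 0.894) and Ifnb1 (0.06, adjusted p = 0.827) did not pass.

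Among the lists, interferon response genes had a lower effect of LIST LPS at 24 h in 15 of 24 and a higher one in 1, 17 and 2 over the list alone (median -1.13, adjusted p = 1.7e-08, and 0.146 estimated), and cytokines in 7 of 18 (median -0.64, adjusted p = 0.00192, and 0.146 estimated). Chemokines were lower in 4 of 15, 6 over the list alone (mean -1.04, median near 0, adjusted p = 0.00544, and 0.146 estimated). Glycolysis genes were lower in 13 of 20 (median -0.73, adjusted p = 5.7e-07, and 0.00688 estimated). Oxidative phosphorylation genes were lower in 14 of 35 (median -0.61, adjusted p = 1.36e-07), ribosomal protein genes in 20 of 46 (median -0.57, adjusted p = 1.72e-07), macrophage identity genes in 11 of 28 (median -0.73, adjusted p = 7.21e-06) and lysosomal genes in 8 of 25 (median -0.43, adjusted p = 0.00344). With an estimated correlation these had an adjusted p = 0.214 for ribosomal proteins and 0.146 for the others. TLR receptors (6 of 20 lower), antigen presentation (5 of 24), NF-kB (5 of 16), oxidative stress (7 of 24) and matrix proteases (5 of 20) also passed, with an adjusted p between 0.00347 and 0.0251, and between 0.146 and 0.267 with an estimated correlation. Lymphocyte markers were higher in 7 of 15 (adjusted p = 0.00407, and 0.146 estimated). In the direct difference, which uses no media, the direction of the lysosomal (adjusted p = 0.523) and matrix protease lists (adjusted p = 0.922) turned. A change with time in culture alone is not removed there. Chemokines (adjusted p = 0.119), macrophage identity (adjusted p = 0.0516) and lymphocyte markers (adjusted p = 0.259) no longer passed, and ribosome biogenesis (adjusted p = 3.4e-06) and cholesterol synthesis (adjusted p = 0.00671) newly passed as lower. Without LIST LPS 24 h replicate 3, 1714 genes passed and without LIST LPS 6 h replicate 3, 1740, in place of 2735. In the direct difference 5364 passed, and with scan period as a random block 1185.

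The effect of Sigma LPS differed between the times for 2085 of 16001 genes, 1010 higher and 1075 lower at 24 h, of which 161 and 444 differed at least 2-fold. Late genes were Lcn2 (3.99, SE 0.39, held down by saturation), Il6 (3.20, SE 0.20, adjusted p = 7.25e-09), the caspase gene Casp9 (3.07, likewise), Il1a (2.96, SE 0.37), Ptgs2 (2.71, SE 0.64), Tnf (2.27, SE 0.69, adjusted p = 0.0446), Btrc (2.21), Stfa2 (2.20), Foxp1 (2.12), Zbtb48 (2.11) and Ccl5 (2.00, SE 0.32). Lower at 24 h were Il10 (-3.87, SE 0.46), the coagulation factor gene F10 (-4.04), COX2 (-4.12), Ccl3 (-3.20, SE 0.67), the glutamine transporter Slc1a5 (-2.87), Prss22 (-2.84), Lamp1 (-2.80), Scd2 (-2.66) and Cebpd (-2.65). Cxcl10 (-2.14, adjusted p = 0.0235) and Cd14 (-1.65, adjusted p = 0.0494) were lower as well, though Cxcl10 took the opposite sign with the processed signals of the scanner software (0.34). Il1b (0.43, adjusted p = 0.743, but -0.97 without the Cy3 array of Sigma LPS 6 h replicate 1), Nos2 (-0.58, adjusted p = 0.355), Ifnb1 (-0.04, adjusted p = 0.877) and Tlr4 (-0.07, adjusted p = 0.835) did not pass.

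Glycolysis genes had a lower effect of Sigma LPS at 24 h in 12 of 25, 16 over the list alone (median -0.77, adjusted p = 1.05e-09, and 0.00465 estimated). Cell cycle genes were lower in 16 of 43 and higher in 2 (median -0.53, adjusted p = 1.36e-06, and 0.345 estimated), and cholesterol synthesis genes lower in 9 of 21, 10 over the list alone (adjusted p = 0.000252, and 0.171 estimated). Ribosomal protein genes were lower in 16 of 51 (median -0.50, adjusted p = 2.19e-06), interferon response genes in 8 of 35 and higher in 1 (median -0.32, adjusted p = 0.00149), macrophage identity genes lower in 9 of 31 and chemokines in 4 of 15. With an estimated correlation these had an adjusted p = 0.345, 0.583, 0.345 and 0.345. Matrix proteases (8 of 26 lower), oxidative phosphorylation (11 of 36), immediate early factors (6 of 29), lysosome (7 of 31), osteoclast (3 of 13) and antigen presentation (3 of 24) also passed, with an adjusted p between 0.00149 and 0.0322, and between 0.171 and 0.415 with an estimated correlation. Unfolded protein genes had a higher effect at 24 h in 5 of 25 and a lower one in 1 (median 0.28, adjusted p = 0.00279, and 0.345 estimated). Without Sigma LPS 24 h replicate 1, 1341 genes passed and without its replicate 3, 1381, in place of 2085. The lysosomal list turned against media replicates 4 to 6 alone (adjusted p = 0.956) and with replicates 1 to 3 for LIST LPS and 4 to 6 for Sigma LPS (adjusted p = 0.971). With no batch term 658 genes passed and with the media replicates of 1 array left out 620.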

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

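Tests of explanations in this part, but for brightness in the ribosomal protein genes, were chosen after seeing the results they concern. The bound for scan period in these genes was tightened after its value was seen. The tests of the difference were planned.

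In other splits of the same cultures the highest count was 1648 for LIST LPS at 6 h, 3212 for Sigma LPS at 6 h, 4243 for LIST LPS at 24 h and 3267 for Sigma LPS at 24 h, against real counts of 1485, 3198, 6337 and 2851. As many genes as in the real split, itself counted, came from 2, 2, 1 and 2 of 84 splits, shares under 0.05. At 6 h many splits mix batches, so chance stays open there. The splits exchange single cultures and so do not weigh scan period, within which cultures correlated at 0.38. For LIST LPS at 24 h the highest other split took media replicates 1 to 3, which share a scan period, and with scan period as a random block the real count was 2563. A fixed block cannot be fitted there, so scan period stays open for this count. At 6 h the highest splits took media replicates 1 to 3 (LIST LPS) or 4 to 6 (Sigma LPS) as the treated group, which with the batch term compares the same cultures again. For Sigma LPS at 24 h the highest split set media replicates 4 to 6, which were scanned in a period of their own, against the rest. With scan period as a fixed block the real count was 2662. For the change of the LIST LPS effect with time 3 of 100 splits reached the real count of 2735 (highest other 4338, a split that kept the LIST LPS 24 h cultures together), and for Sigma LPS 1 of 100 reached 2085 (highest other 1677). These shares carry the same limits. With scan period as a random block the LIST LPS count was 1185, and no fit with it as a fixed block can be had. For the differences between preparations there are 10 splits, too few for a share under 0.05. The real counts were 867 at 6 h and 4048 at 24 h and the highest others 6 and 5.

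The first pattern weighed is the difference between the preparations at 24 h, seen in 4048 genes by the test of the difference. In untreated cells of the same pair of scan periods 77.7% of 4036 of these genes had the same sign, against 59.5% of genes that did not differ, and the values correlated at r 0.737 across genes. Against untreated cells of the own scan period 935 genes (23.6%) still differed in the same direction, among them Il6 and Hspa1a. Scan period and preparation therefore cannot be told apart for the set as a whole, because the LIST LPS 24 h arrays share no period with media of 24 h and the untreated cells of their period had been cultured for 6 h. Picked after seeing their values, Il6 (3.21 and 3.17), Hspa1a (-4.06 and -3.84), Timp1 (-3.18 and -3.44) and Cxcl10 (-2.65 and -2.36) kept their difference. Untreated cells differed by 0.04, -0.21, 0.26 and -0.29, but also in time in culture. Genes picked this way cannot weigh scan period against preparation.

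The second pattern is the fall of ribosomal protein and oxidative phosphorylation genes with LIST LPS at 24 h, medians -0.61 and -0.69. Among 10000 random lists matched on brightness the medians lay at percentiles 0.01 and 0. Against untreated cells of the same scan period the medians were -0.32 (SE 0.07, percentile 5.99, adjusted p = 9.92e-05) and -0.56 (SE 0.16, percentile 0, adjusted p = 1.22e-06). The percentiles argue against a brightness trend for oxidative phosphorylation and leave it open for ribosomal proteins. Neither median lies over 2 standard errors beyond the bound of -0.3, so scan period cannot be told apart from LIST LPS in either list. The time in culture of the untreated cells, 6 h in that setting, was not tested.

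The following genes differed between the preparations or the times by the test of the difference. The 5 largest in each direction and those of the fixed genes that passed are given. At 6 h, Sigma LPS against LIST LPS, 867 genes differed, among them Plpbp (3.03), COX2 (2.90), Ahsa1 (2.88), H1f8 (2.83), Slc39a11 (2.83), Clvs1 (-4.11), Eny2 (-3.58), Dsg3 (-3.54), Ccl22 (-3.18), Ift52 (-2.81) and Ccl5 (-1.29). The sizes for Plpbp, H1f8 and Slc39a11, saturated on every LIST LPS 6 h array, are not known. Nor is that of Clvs1, not well above background with Sigma LPS. At 24 h these were Sqstm1 (4.28), Wfdc18 (3.62), COX2 (3.61), Rps27a (3.46), Vim (3.43), Hspa1a (-4.06), Slc26a11 (-3.95), Cenpm (-3.80), Serpinb9c (-3.75), Npr3 (-3.66), Tnf (2.20), Il6 (3.21), Nos2 (-0.84), Cxcl10 (-2.65), Tlr4 (0.38) and Cd14 (2.01). Between the times with LIST LPS they were Hspa1a (4.11), Kbtbd11 (3.51), Npr3 (3.42), Capn5 (3.41), Cenpm (3.36), COX2 (-4.83), Ccl3 (-4.43), Vim (-4.26), Rps27a (-3.70), Ccl22 (-3.59), Il6 (-0.65), Il10 (-3.17), Tlr4 (-0.60) and Cd14 (-2.41). Between the times with Sigma LPS they were Lcn2 (3.99), Il6 (3.20), Casp9 (3.07), Il1a (2.96), Ptgs2 (2.71), COX2 (-4.12), F10 (-4.04), Il10 (-3.87), Ccl3 (-3.20), Slc1a5 (-2.87), Tnf (2.27), Cxcl10 (-2.14), Ccl5 (2.00) and Cd14 (-1.65), of which Lcn2 and Casp9 were saturated on 0.83 of the Sigma LPS 24 h arrays.

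Kif23 in media 24 h replicate 6 stood at -0.04, away from the other 3 measured media cultures (1.1 to 1.3). In this way 66 groups of media values of a gene were examined and 1 was found, while chance alone flags about 1 in 20 groups. Spots with the software's outlier flag, left out elsewhere, gave Il1b at 6.58 (adjusted p = 8.43e-10) and Ptgs2 at 6.15 (adjusted p = 1.34e-11) with LIST LPS at 6 h. At 24 h with LIST LPS they gave Il1b at 4.93 (adjusted p = 4.14e-09) and Ptgs2 at 5.44 (adjusted p = 7.33e-12). With Sigma LPS at 24 h they gave Acod1 at 3.94 (adjusted p = 1.78e-08) and Isg15 at 0.63 (adjusted p = 0.000179), both named after their values were seen, while Tlr2 stood at 0.27 (adjusted p = 0.204) with LIST LPS at 6 h and 0.16 (adjusted p = 0.324) with Sigma LPS at 24 h.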

How the results depend on the processing

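The alternatives that kept the outlier-flagged spots, left out the Cy3 array of Sigma LPS 6 h replicate 1, or used the scan period as a block or to choose untreated cells were chosen after seeing the data. The others were planned. Over all alternatives 17767 values of the 400 gene results kept their direction and side of the threshold. Of the rest 295 (in 76 results) no longer passed, 82 newly passed and 18 changed sign. For 208 list results, 9541 values kept theirs, 263 no longer passed, 160 newly passed and 13 changed sign. Quantile normalising average intensities, counted too, cannot alter ratios. Replicate numbers do not pair the cultures, as deviations of like-numbered cultures correlated at -0.244 to 0.152. With replicate number as a block within each time point, LIST LPS at 24 h gave 6193 genes, LIST LPS at 6 h 1621, Sigma LPS at 24 h 2286 and r at 24 h was 0.609. That block could not be fitted for Sigma LPS at 6 h, its difference from LIST LPS or its change with time, and scan period as a fixed block could not for LIST LPS at 24 h, Sigma against LIST LPS at 24 h or the change of LIST LPS with time.

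Where a cause is not given below, the cause was not tested. With the requirement of a signal well above background on every array, which tests fewer genes, the counts were 774 (LIST LPS 6 h), 2030 (Sigma LPS 6 h), 3473 (LIST LPS 24 h), 1543 (Sigma LPS 24 h), 557 (Sigma against LIST LPS 6 h), 2137 (24 h), 1320 (LIST LPS over time) and 1325 (Sigma LPS over time). With a further limit of 2-fold, by its construction lower, they were 457, 590, 1222, 488, 350, 695, 963 and 605. With flagged spots kept they were 2412 for LIST LPS 6 h, 4643 for Sigma LPS 24 h, 1847 and 6822 for Sigma against LIST LPS at 6 h and 24 h, and 4787 and 3494 for the changes of LIST and Sigma LPS over time. Without a batch term they were 2388 for LIST LPS 6 h, 1684 for Sigma LPS 24 h, 4526 and 2623 for Sigma against LIST LPS at 6 h and 24 h, and 658 for Sigma LPS over time, and r at 6 h was 0.239.

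The series matrix gave 5911 genes for Sigma LPS 6 h, 2606 for Sigma against LIST LPS 6 h and 4383 for Sigma LPS over time. The processed signals of the scanner software without loess gave 5099 and 1584 for the first and second of these, and median centring gave 521 for Sigma against LIST LPS 6 h. With the media replicates of a single array left out the counts were 890 (Sigma LPS 6 h), 246 (Sigma against LIST LPS 6 h) and 620 (Sigma LPS over time), with fewer cultures. Within batch 2 alone Sigma LPS 6 h gave 1542 and with only the groups of the comparison 2127. With scan date as batch LIST LPS 6 h gave 946. Array weights gave 5068 for Sigma LPS 24 h, 4233 for LIST LPS over time and r 0.592 at 24 h. With media 1 to 3 for LIST LPS and 4 to 6 for Sigma LPS, Sigma against LIST LPS 6 h gave 1377 and r at 24 h was 0.125. Media replicates 4 to 6 alone gave 4219 for LIST LPS 24 h, and replicates 1 to 3 alone r 0.61.

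Scan period as a random block gave 2563 (LIST LPS 24 h), 1185 (LIST LPS over time), 750 (Sigma against LIST LPS 24 h) and r 0.589, and as a fixed block 1385 for Sigma against LIST LPS 6 h. Untreated cells of the same scan period gave 5364 for LIST LPS over time, 1862 for Sigma against LIST LPS 24 h and r 0.625. Of the 92 list results that passed of 208, 25 did so with an estimated correlation, which allows for more shared movement of genes, and fry passed 112.

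Genes changed sign without a batch term in Sigma against LIST LPS at 6 h: Ahsa1 (-0.83), Slc39a11 (-0.66), Klhl3 (-0.44), Akt1s1 (-0.36), Fmc1 (-0.25), Plpbp (-0.16), COX2 (-0.14) and Gp1bb (-0.05), and so did Cdk2 with LIST LPS at 6 h (0.17). Cxcl10 changed sign in Sigma LPS over time with the processed signals (0.34) and the series matrix (1), Il1b there without the dim Cy3 array (-0.97) and Il6 in LIST LPS over time with the series matrix (0.01). With untreated cells of the same scan period Psap (0.07) and Rps27a (0.04) changed sign for LIST LPS 24 h, and Vim (-0.61), Rps27a (-0.26) and Rps27 (-0.03) for Sigma against LIST LPS 24 h.

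Lists changed direction with untreated cells of the same scan period for lysosome (adjusted p = 0.414 for LIST LPS 24 h, 0.523 over time, 0.000167 for Sigma against LIST LPS 24 h), macrophage identity (0.999, LIST LPS 24 h), matrix proteases (0.922, LIST LPS over time) and LXR and lipid efflux (0.0156, Sigma against LIST LPS 24 h). Lysosome in Sigma LPS over time changed with media 1 to 3 for LIST LPS and 4 to 6 for Sigma LPS (0.971) and media 4 to 6 alone (0.956), and cell cycle with media 4 to 6 alone (0.659, LIST LPS 24 h) and with that division of the media (0.00234, Sigma against LIST LPS 24 h). Granulocyte and erythroid markers changed for LIST LPS 24 h with signal on every array (0.821), and without a batch term oxidative phosphorylation (0.0132) and ribosomal proteins (0.379) did in Sigma against LIST LPS 6 h.

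Leaving out each culture in turn gave 1018 to 1727 genes for LIST LPS 6 h, 2145 to 3390 for Sigma LPS 6 h, 4273 to 6826 for LIST LPS 24 h, 1716 to 3300 for Sigma LPS 24 h, 459 to 1191 for Sigma against LIST LPS 6 h, 2582 to 4523 for 24 h, 1714 to 3150 for LIST LPS over time and 1341 to 2353 for Sigma LPS over time. The range of r was 0.406 to 0.545 at 6 h and 0.511 to 0.559 at 24 h, and 87 to 97 list results passed. Counts moved by over 1.5 times without LIST LPS 6 h replicate 2 (459), media 6 h replicate 1 (549) or 4 (569) in Sigma against LIST LPS 6 h, without LIST LPS 24 h replicate 3 in Sigma against LIST LPS 24 h (2582) and LIST LPS over time (1714), without LIST LPS 6 h replicate 3 in the latter (1740). They also did so without Sigma LPS 24 h replicate 1 in Sigma LPS 24 h (1716) and over time (1341), and without its replicate 3 over time (1381). Without the Cy3 array of Sigma LPS 6 h replicate 1 no count moved by over 1.5 times (3535 for Sigma LPS 6 h).

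Signal over background limits what can be read in Sigma LPS at 6 h, where 321 genes were not well above background on any array. The software's criterion for this was set at 13 in batch 2 and 2.6 in batch 1, so this number is not comparable with the 43 of LIST LPS at 6 h, and the filter and the requirement above were stricter in batch 2. With LIST LPS at 6 h 62 genes were saturated on every array, against 0 with Sigma LPS. Of the genes given above for a change of sign without a batch term Plpbp, Slc39a11, Fmc1, Gp1bb and Akt1s1 were saturated there.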

Other observations

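The test in the last paragraph below was chosen before seeing its result. The genes in the next paragraph were chosen after seeing their values.

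A shared core of genes rose in 3 of the 4 LPS effects: 60 genes rose at least 2-fold with LIST LPS at 6 h and 24 h and with Sigma LPS at 24 h. Of these, 51 also rose with Sigma LPS at 6 h and 9 did not pass there. The 60 were selected on the other 3 effects and the 9 for not passing there. Low values of the 9 thus follow in part from the selection. Among the 9 was Dsg3 at 3.64 with LIST LPS and 0.10 with Sigma LPS at 6 h, then 2.80 and 1.42 at 24 h. Others were Shox2 (2.89 and 0.28, then 1.86 and 1.13) and Wnt5a (2.08 and -0.06, then 2.56 and 1.99). Casp9 (1.36 and -0.41, then 2.04 and 2.66) and Nfkbib (1.13 and 0.05, then 1.46 and 1.41) followed the same course. Casp9 was saturated on 0.67 of the LIST LPS 6 h and 0.83 of the Sigma LPS 24 h arrays. Sigma LPS at 6 h was the only LPS group in batch 2, so batch and preparation cannot be told apart. No explanation was tested.

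Untreated cells differed among themselves. Media replicates 4 to 6 and 1 to 3 were read on separate scanners. At 24 h the former differed in 1474 of 12108 genes (388 higher, 1086 lower). At 6 h, with other software and array design too, it was 7428 of 17960 (3719 higher, 3709 lower).

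For the Sigma LPS 6 h arrays, where 1 label field states 24 h, RNA collected at 24 h was tested. Across genes that differ between the times with LIST LPS, the effect in the 3 Sigma LPS 6 h cultures correlated with that of LIST LPS at 6 h at r 0.40, 0.61 and 0.67 and with that at 24 h at r 0.00, -0.16 and 0.06. The lowest difference in r was 0.4. The Sigma LPS 24 h mean gave r 0.43 and 0.56, the latter raised by media shared with LIST LPS 24 h. All 3 cultures lay nearer LIST LPS at 6 h, but the collection time stays open. Genes are not independent replicates.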
